A study of Mus musculus with 5 samples.

How the data were processed

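Total RNA was extracted with RNeasy columns and amplified and labelled with Cy3 by a whole-transcriptome system, per the labels' protocols. Each of the 5 samples was hybridised to 1 one-colour Agilent array. The deposited scanner tables hold background-subtracted, processed spot intensity on a linear scale, made with Agilent Feature Extraction 11.5.1.1, per the file headers. A series table deposited by the authors holds log2 values of the same spots. Each of its columns equalled the log2 processed intensity of its own array plus a constant (3.10 and 3.06 for the Arid1a-deficient arrays and 3.39, 3.41 and 3.35 for the Brg1-deficient arrays). Its scale and direction were thereby known, and how the constants were chosen stays unknown. The column medians were 8.30, 8.12, 8.36, 8.51 and 7.79.

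Each array carried 62976 spots, of which 59305 were not controls. Control spots and spots with an outlier mark were left out, spots of 1 probe were averaged on the log2 scale, and 10 of 55681 probes with an outlier on an array were dropped. The main scaling was the log2 processed signal minus the array's 75th percentile of it over non-control probes. Probe accessions without versions were matched to a RefSeq gene table (assembly GRCm38.p6, used only for names and gene order, since the arrays name another build). Of 55671 probes, 28020 had 1 gene symbol, 0 had several and 27651 were left with the name in the file. Where a gene had several probes, the one with the highest mean over all 5 arrays stood for it, and different probes of a gene could disagree, as they did in size for Arid1a. Of the resulting 36794 genes and unnamed transcripts, 27500 were well above background on at least 2 of the 5 arrays and were tested, 16363 of them with a symbol.

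Genotypes were taken from the sample titles. The only comparison was Arid1a-deficient (2 arrays) minus Brg1-deficient (3 arrays), tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3 without covariates (3 residual and 2.78 prior degrees of freedom), at a Benjamini-Hochberg adjusted p under 0.05. A probe not well above background on any array of a genotype was given a bound ("at least N-fold"): the mean of the brighter group against the mean, per array of the dimmer group, of the higher of the lowest signal well above background and the probe's own. Thresholds, designs, alternatives, the rule for named genes and 39 gene lists were fixed before the data were examined. The lists covered SWI/SNF subunits, epithelial lineages, other cell types, signalling and stress programs and technical markers, with 806 genes in all, 697 of them tested, and 19 genes on more than 1 list. Lists were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the lists, and beside it with the correlation estimated (0 lists past the threshold, and 0 at an unadjusted p under 0.05) and with fry. The fry test gave 0 lists past the threshold (8 at an unadjusted p under 0.05) for a shift on balance in one direction and 18 lists for changes in either direction. Neither form of fry compares a list with the other genes.

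The rule for named genes took all probes of Arid1a and Smarca4. In each direction it took the 12 called genes with a symbol, other than Gm, LOC and Rik names, of largest difference whose groups did not overlap, filled with the genes of smallest unadjusted p where fewer passed. From each list it took the called members, at most 4 per direction, or the 2 members of smallest p, which are printed for part of the lists only. It also took Sox9, Krt19, Muc5ac, Muc6, Muc1, Tff1, Tff2, Cdx2, Pdx1, Gata6, Trp63 and Hmga2 whatever their values.

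The test was checked on simulated data with the real means and spreads of 27500 genes, 200 of which were changed, in 10 runs of 2 against 3 arrays. It recovered 0% of genes changed by 1 on the log2 scale, 19.4% of those changed by 2, 90.8% of those changed by 4 and 98.6% of those changed by 6, and called 7.9 unchanged genes per run. With independent simulated genes, camera called 0 of 39 lists when none was shifted and found a shift of -1 in the fibroblast list in 100% of 20 runs.

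The arrays lay on 2 slides scanned in 2 sessions, 0 of which held both genotypes, so a slide block could not be fitted. Correlations over genes were 0.932 between the Arid1a-deficient arrays, 0.950 to 0.976 among the Brg1-deficient arrays and 0.917 to 0.930 between genotypes, so no 2 arrays were copies. The alternatives tried were normexp background correction with an offset of 50 (on the median spot signals, in place of the planned mean signals, which the tables do not hold), quantile normalization, median scaling, the series table, other filters on dim probes, every probe on its own, the mean over probes, an intensity trend with robust eBayes, array weights, a floor, the replicate number as a block, each array left out in turn, and cyclic loess, added after seeing the data. Probe choice and tested genes were kept as in the main setting unless the alternative changed them.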

Results

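RNA from the epithelium of intraductal papillary mucinous neoplasms (IPMN), the mucin-producing cystic lesions of the pancreatic ducts, was measured on 5 one-colour Agilent mouse arrays. All mice carried Ptf1a-Cre, which recombines in the embryonic pancreas, together with an oncogenic Kras allele. In 2 mice the floxed gene was Arid1a, a subunit of the SWI/SNF chromatin remodelling complex, and in 3 mice it was Brg1, the ATPase of the same complex, whose gene symbol is Smarca4. The labels describe the lesions as coming from that many mice, so each array stood for 1 animal. The 75th percentile of the processed signal was 189 and 183 intensity units on the Arid1a-deficient arrays and 159, 165 and 134 on the Brg1-deficient arrays. Between 58.6% and 69.0% of 55671 probes were well above background, the lowest share being that of Brg1-deficient replicate 3, and no spot was saturated. The number of arrays limited the precision. The Arid1a-deficient arrays lay on 1 slide and in 1 scan session and the Brg1-deficient arrays on another slide and in another session, so that slide and genotype cannot be told apart in any comparison given here. All levels are log2 processed signals relative to the 75th percentile of the array, and all differences are Arid1a-deficient minus Brg1-deficient.

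The targeted genes were examined first, on every probe. Both probes of Arid1a read lower in Arid1a-deficient IPMN. The brighter of them, A_66_P116888, was at 0.51 and -0.51 in the Arid1a-deficient samples and at 2.04, 1.62 and 1.91 in the Brg1-deficient samples, a difference of -1.86 (SE 0.40, 3.62-fold). The other, A_55_P2167769, was at -1.67 and -0.87 against -0.51, -0.43 and -0.53, a difference of -0.78 (SE 0.35). With 1 array left out, this difference lay between -1.18 and -0.38, and that of the brighter probe between -2.37 and -1.34. Both probes of Smarca4 read lower in Brg1-deficient IPMN. Probe A_55_P2154684 was at 0.92 and 0.64 in the Arid1a-deficient samples and at -0.41, -0.93 and -1.19 in the Brg1-deficient samples, a difference of 1.62 (SE 0.35, 3.08-fold). Probe A_55_P2154690 was at 0.73 and 0.19 against -1.12, -1.58 and -1.79, a difference of 1.96 (SE 0.36, 3.88-fold). On all 4 probes the samples of the groups did not overlap, in the direction that their labels give. Such a lack of overlap was also seen for 36.8% of all tested genes. The groups were compared with each other only, so the genotype of a single sample was not tested. Over all probes limma called 0 of the 4 (3 had an unadjusted p under 0.05), with adjusted p of 0.149 and 0.322 for Arid1a and 0.148 and 0.115 for Smarca4. All 4 probes stayed well above background in every sample, and whether they lie in the floxed exons is not given in the sources used here.

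**Figure D1:**
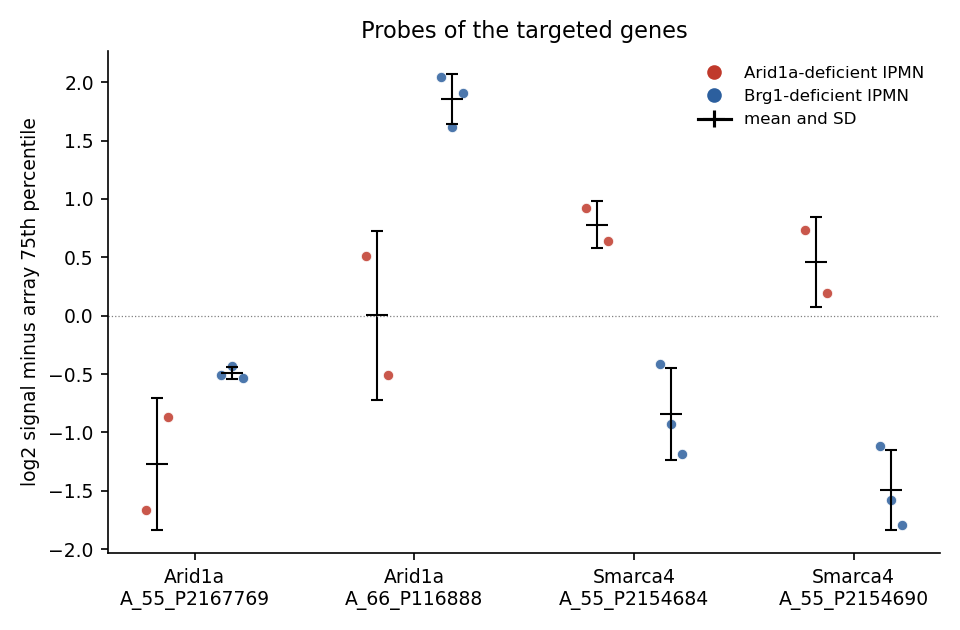
Level of each probe of Arid1a and Smarca4 in each sample, as log2 signal minus the 75th percentile of the array, with the mean and SD of 2 Arid1a-deficient and 3 Brg1-deficient samples. On each probe the samples of the deficient genotype lie below the others, by 0.78 to 1.96 on average.

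Over the 27500 genes and unnamed transcripts tested, the comparison of the genotypes called 15, of which 3 were higher and 12 lower in Arid1a-deficient IPMN. Kif5c, which encodes a kinesin heavy chain, was lower by the widest margin, with a mean of -3.11 ± 0.11 (SD, n = 2) against 2.59 ± 0.38 (SD, n = 3), a 52.1-fold difference (SE 0.33 on the log2 scale, limma adjusted p = 0.0373). Gp2, a zymogen granule glycoprotein of acinar cells, was at -2.14 ± 0.38 against 3.09 ± 0.51, a 37.5-fold difference (SE 0.40, adjusted p = 0.0470). Afp, the fetal serum protein alpha-fetoprotein, was higher, at 0.60 ± 1.19 against a signal not well above background in any Brg1-deficient sample, which made it at least 25.0-fold higher (adjusted p = 0.0470). The bound was 44.9-fold without Arid1a-deficient replicate 1 and 13.9-fold without replicate 2. The remaining called genes with a symbol under the naming rule were lower and not well above background in both Arid1a-deficient samples. They were Slc22a1, an organic cation transporter (at least 9.11-fold), the transcription factor gene Klf14 (at least 6.06-fold), St8sia2, a polysialyltransferase (at least 4.81-fold), the adaptor gene Sla (at least 3.73-fold), Aox3, an aldehyde oxidase (at least 3.43-fold), and Prrg3 (at least 3.20-fold). Their adjusted p lay between 0.0373 and 0.0489. The other calls higher in Arid1a-deficient IPMN, named here after their values were seen, were Gm6377 (at least 2.74-fold) and 9030612E09Rik (at least 3.14-fold). For every gene given with a bound, here and below, the p-value tests the signals as measured and not the bound. With signals raised to the lowest one well above background on each array, only Kif5c, Gp2 and an unnamed transcript were called.

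**Figure D2:**
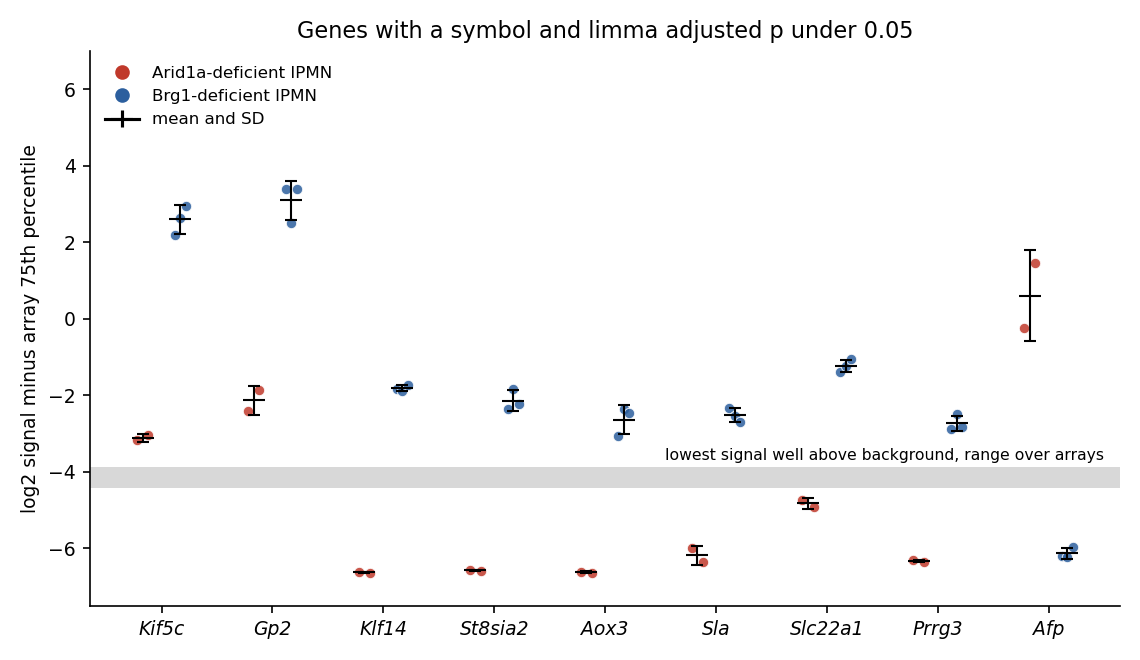
Level of the called genes with a symbol, other than Gm and Rik names, in each sample, as log2 signal minus the 75th percentile of the array, with the mean and SD of each genotype. Kif5c and Gp2 were well above background in all 5 samples, while each of the other genes lay below the grey band, the range over arrays of the lowest signal well above background, in one genotype.

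Further genes named by the smallest unadjusted p did not pass the threshold. Higher values in Arid1a-deficient IPMN were those of Ifi202b, an interferon-inducible gene, at 1.64 ± 1.04 against no signal well above background in the Brg1-deficient samples (at least 51.3-fold, limma adjusted p = 0.0543, the bound being 85.4-fold without Arid1a-deficient replicate 1 and 30.8-fold without replicate 2), of the phospholipase gene Pla2g5 (at least 6.04-fold, adjusted p = 0.0615) and of the planar cell polarity gene Vangl2, which was well above background in every sample (3.91 and 3.91 against 1.41, 1.39 and 1.65, 5.39-fold, adjusted p = 0.0615). Vangl2 passed with normexp (adjusted p = 0.0445) and with array weights, which did not converge (0.0267), but its difference was 0.35 with the mean over its probes (adjusted p = 0.714). Ifi202b passed with median scaling, the mean over probes, array weights and cyclic loess (adjusted p from 0.0225 to 0.0496). Pramel27, Brca2, Fkbp6, Lipg, Fam171a2 and the olfactory receptor genes Olfr657, Olfr629 and Olfr453 were also on this list, with lower bounds between 1.0-fold and 2.59-fold. Lower values were those of Lrrc17 (at least 7.11-fold), the monoamine oxidase gene Maoa (at least 5.53-fold), Gng4 (at least 3.94-fold) and Hic1 (at least 2.38-fold), with adjusted p between 0.0529 and 0.0543. At an unadjusted p under 0.05, limma counted 2929 genes as higher and 1886 as lower, where 1375 would be expected in all without any difference. The higher genes were 60.8% of these, but 44.9% without Arid1a-deficient replicate 1, 49.1% without replicate 2 and 48.3% with normexp, so that the side with more genes was not stable. The samples of the genotypes did not overlap for 36.8% of genes, and chance gives 20% for 2 samples against 3. Leaving out any 1 of the 5 arrays left 0 limma calls, in designs of 2 against 2 or 1 against 3 arrays, with 2869 to 5395 genes at an unadjusted p under 0.05. The 15 called genes were picked on these same arrays, so refits without 1 array give no separate support for them. In those refits the difference of Kif5c stayed between -5.90 and -5.52. With normexp, which adds an offset to every signal, it was -3.72, that of Gp2 -3.88 and that of Afp 2.37, and the differences of the other called genes under the naming rule lay between -1.11 and -0.60. Of the 15 called genes, 12 were not well above background on any array of one genotype, and requiring a signal well above background on all 5 arrays left Kif5c, Gp2 and an unnamed transcript. The median difference of all tested genes was 0.10, and it fell from 0.35 in the dimmest 5500 genes to 0.04 in the brightest 5500.

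**Figure D3:**
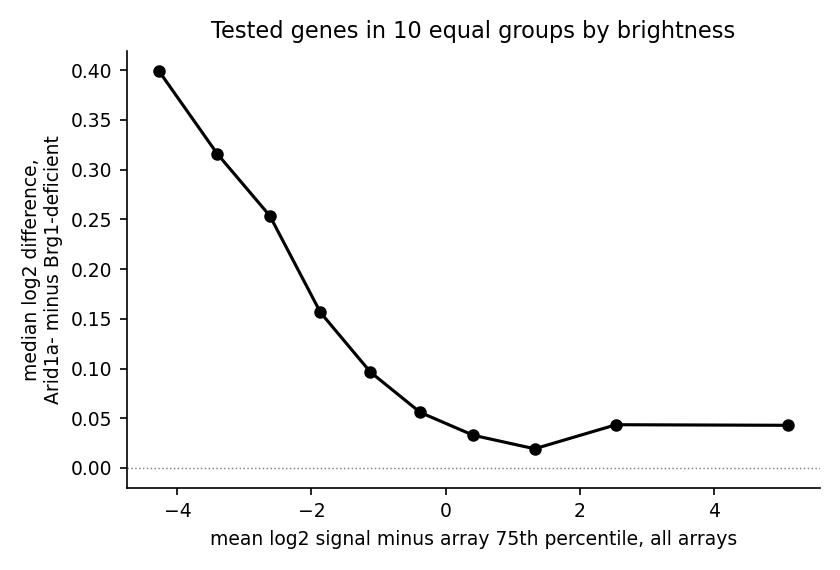
Median log2 difference, Arid1a-deficient minus Brg1-deficient IPMN, of the tested genes in 10 equal groups by mean level (log2 signal minus the 75th percentile of the array). The median was 0.40 in the dimmest group and 0.04 in the brightest.

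Markers of fibroblasts and pancreatic stellate cells read lower in Arid1a-deficient IPMN as a group. The camera test with a preset correlation gave adjusted p = 1.96e-10, and the call was lost with an estimated correlation (adjusted p = 0.599). All 21 tested members were lower, with a median difference of -1.38 (bootstrap 95% interval over genes -1.75 to -1.03), and for 13 of them the samples of the genotypes did not overlap. The matrix protease gene Mmp2 was at -2.29 ± 0.02 (SD, n = 2) against -0.32 ± 0.14 (SD, n = 3), and the membrane glycoprotein gene Pdpn at -2.68 ± 0.36 against 0.00 ± 0.78. Of the collagens, Col6a1 was at 0.76 against 2.24 and Col1a2 at 2.99 against 4.76, both picked after their values were seen. No member passed over all genes tested, and 8 passed when adjusted over the list alone. The median was -0.79 without Arid1a-deficient replicate 1 and -0.92 with normexp.

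The Hox genes, homeobox regulators of body axis identity, were lower by a median of -1.03 over 22 tested members (interval -1.77 to 0.33), 14 of them lower and 8 higher. The adjusted p of camera was 0.00147 with the preset correlation, and the call was lost with an estimated correlation (adjusted p = 0.599). Hoxb5 (at least 4.15-fold) and Hoxd9 (at least 5.10-fold) were not well above background in either Arid1a-deficient sample, both with a limma adjusted p of 0.0615. With such genes at their bound the list median was -0.68. None passed over all genes tested, and adjusted over the list alone 9 passed as lower and 2 as higher. The median was -0.41 with normexp background correction and -0.49 without Arid1a-deficient replicate 1, and the call was lost where a signal well above background was required on all arrays (-0.53).

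Macrophage and myeloid markers were lower by a median of -0.63 over 18 members, 15 of them lower (camera adjusted p = 0.00334). This call and those of the other lists in this paragraph were lost with an estimated correlation, which gave adjusted p = 0.599 here. Ms4a7 was at -0.63 against 0.64, whereas Cd14, the lipopolysaccharide co-receptor, went the other way at 3.55 against 2.32. Genes of the epithelial-mesenchymal transition (EMT) were lower by a median of -0.63 over 14 members (adjusted p = 0.0344, and adjusted p = 0.599 with an estimated correlation). Mmp2, which the fibroblast list also holds, and the receptor tyrosine kinase gene Axl (0.45 against 1.61) had the smallest p. Endothelial markers were lower by a median of -0.57 over 17 members (adjusted p = 0.0411, and adjusted p = 0.599 with an estimated correlation), with Cdh5, the vascular cadherin, at -1.73 against -0.42 and Sox17 in the other direction at 2.18 against -0.70. Adipocyte markers were lower by a median of -1.07 over 8 members (adjusted p = 0.0411, and adjusted p = 0.599 with an estimated correlation), Adipoq being at -3.99 against -2.11 and Cfd at -3.42 against -0.97, each well above background in 1 of the 2 Arid1a-deficient samples. Acinar markers were lower by a median of -0.38 over 26 members (adjusted p = 0.0411, and adjusted p = 0.880 with an estimated correlation), 18 of them lower, and their only called member was Gp2. Erythroid markers were lower by a median of -1.67 over 7 members (adjusted p = 0.0411, and adjusted p = 0.889 with an estimated correlation), yet no member separated the genotypes. Hba-a1 was at 1.71 and 4.42 in the Arid1a-deficient samples and at 3.89, 6.33 and 4.95 in the Brg1-deficient samples. The acinar, erythroid, adipocyte and endothelial calls were also lost under quantile normalization (medians -0.39, -1.77, -1.09 and -0.55), normexp (-0.23, -0.88, -0.58 and -0.37) and cyclic loess (-0.44, -1.80, -1.13 and -0.64). Requiring a signal well above background on all arrays likewise lost them (-0.15, -1.58, -0.73 and -0.57). With no filter the acinar, erythroid, endothelial and EMT calls were lost (medians -0.37, -1.61, -0.57 and -0.45). The erythroid, adipocyte and endothelial calls were lost with every probe on its own (-1.67, -0.73 and -0.50) and with array weights (-0.78, -0.81 and -0.58). Median scaling and the floor lost the endothelial call at medians of -0.59 and -0.57, and camera on ranks, at the main medians, the acinar, adipocyte and EMT calls. The EMT median was -0.37 with normexp, and the acinar median -0.71 with array weights. Without Arid1a-deficient replicate 1 the acinar, erythroid and endothelial calls were lost (medians -0.19, -0.38 and -0.27), and without Arid1a-deficient replicate 2 the EMT call (-0.51), while the acinar and erythroid medians became -0.68 and -3.06. Without Brg1-deficient replicate 1 the acinar call was lost (-0.21), without replicate 2 the acinar, erythroid, adipocyte and endothelial calls (-0.42, -0.82, -0.99 and -0.64), and without replicate 3 the EMT, erythroid, adipocyte and endothelial calls (-0.29, -1.92, -0.98 and -0.49), the acinar median then being -0.74.

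**Figure D4:**
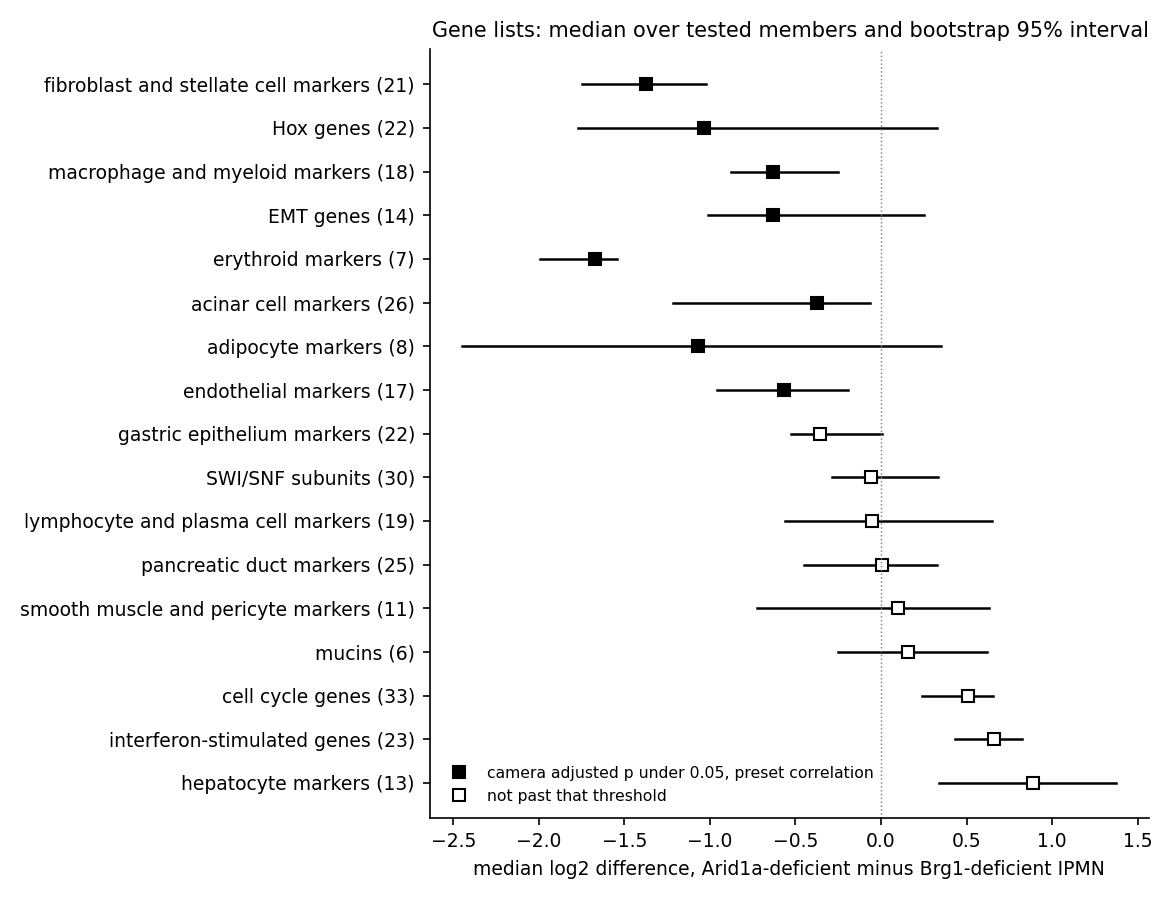
Median log2 difference, Arid1a-deficient minus Brg1-deficient IPMN, over the tested members of 17 gene lists (number of members in brackets), with bootstrap 95% intervals over genes. Filled squares mark the 8 lists past the camera threshold with a preset correlation, all below 0, and the open squares lists that did not pass.

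The duct and mucin lists did not pass as groups. The duct list had a median of 0.01 over 25 members (camera adjusted p = 0.967), with 13 higher and 12 lower, a sign that turned under quantile normalization, median scaling, the series matrix values, cyclic loess and every probe on its own, and without either Arid1a-deficient array or Brg1-deficient replicate 2 (-0.03, -0.04 and -0.09). For 9 of its members the samples of the genotypes did not overlap, 4 being higher and 5 lower, and none was called. Of smallest p were Scnn1a, an epithelial sodium channel subunit, at -1.22 against -2.64 (limma adjusted p = 0.122), and Pkhd1, the polycystic kidney disease gene, at -1.36 against -3.69 (adjusted p = 0.141, well above background in 1 of the 3 Brg1-deficient samples). Of the lineage genes given whatever their values, the duct keratin gene Krt19 was at 5.80 ± 0.09 (SD, n = 2) against 5.83 ± 0.30 (SD, n = 3), and Sox9, a duct progenitor transcription factor, at 2.82 ± 1.15 against 3.27 ± 0.38. Muc1 was at 5.64 against 5.40, the gastric mucin gene Muc5ac at 2.48 and 4.72 against 3.44, 3.91 and 4.94, Tff1 at 9.36 against 9.09 and Tff2 at 7.95 and 9.82 against 8.99, 8.39 and 9.26. Pdx1 was at 3.44 against 3.30, Gata6 at 1.40 against 1.79, Trp63 at 6.34 against 6.33 and Hmga2 at 0.08 against -0.62. None of these passed, with limma adjusted p from 0.272 for Hmga2 to 0.999 for Tff2. Leaving out 1 array turned the direction of Krt19, Sox9, Muc5ac (-1.62 to 0.63), Tff1, Tff2 (-0.93 to 0.94), Pdx1 and Trp63, but not of Muc1, Gata6 and Hmga2. Over all alternatives the difference of Trp63 lay between -0.08 and 0.67. Cdx2 was well above background in Brg1-deficient replicate 1 alone and was not tested, and no probe could be named Muc6. The mucin list had a median of 0.16 over 6 members and the gastric list one of -0.36 over 22 (adjusted p = 0.967 and 0.154), with Cblif, gastric intrinsic factor, at -3.88 against -0.93. The gastric list passed as lower without Arid1a-deficient replicate 2 (median -1.02, adjusted p = 0.000181) and without Brg1-deficient replicate 1 (-0.56, 0.0212), and its median was 0.27 without Arid1a-deficient replicate 1. The intestinal list had a median of 0.41 over 17 members (adjusted p = 0.838), and its member with the smallest p, the goblet cell gene Tff3, was at 1.64 against 5.45 (14.0-fold lower, adjusted p = 0.111). The log2 difference of Tff3 lay between -4.62 and -3.00 with 1 array left out. Squamous and basal keratinocyte genes had a median of 0.51 over 14 members (adjusted p = 0.156), with Ly6d at 5.83 against 2.49 and Krt6b at -1.50 against -3.05. Endoderm transcription factors had a median of -0.19 over 17 members (adjusted p = 0.161). Their median was -0.05 without Arid1a-deficient replicate 1 and -0.34 without replicate 2 or with cyclic loess. The mucin median was 0.53 without Arid1a-deficient replicate 1 and 0.0043 without replicate 2. The intestinal median was 0.74 without Arid1a-deficient replicate 1, 0.23 without Brg1-deficient replicate 2 and 0.05 with normexp, and the squamous median 0.81 without Arid1a-deficient replicate 2 and 0.04 with normexp.

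SWI/SNF subunit genes had a median of -0.06 over 30 members, with Arid1a and Smarca4 themselves the members of smallest p. Of the signalling and growth programs, none passed camera in the main setting. Interferon-stimulated genes had a median of 0.66 over 23 members (camera adjusted p = 0.156), Oas2 being at -1.07 against -2.95 and Oas1a at 1.33 against -0.26. The list passed as higher with the mean over probes (adjusted p = 0.0409) and without Arid1a-deficient replicate 2 (median 0.77, adjusted p = 0.0150), and its median was 0.18 with normexp. Cell cycle genes had a median of 0.51 over 33 members (adjusted p = 0.177), the replication helicase gene Mcm5 being at 2.16 against -0.29. They passed as higher with array weights (median 0.66, adjusted p = 0.0304) and without Brg1-deficient replicate 3 (0.75, 0.0176), and their median was 0.23 with normexp. PI3K and mTOR pathway components had a median of -0.02 over 28 members (adjusted p = 0.512). Tsc2, the inhibitor of mTORC1 signalling, was at -2.54 against -0.51 in that list (adjusted p = 0.107), and 1 member passed as lower when adjusted over the list alone. The mTORC1-responsive metabolic genes had a median of 0.21 over 26 members (adjusted p = 0.911). Wnt targets were at -0.75 (16 members, adjusted p = 0.0886), Notch genes at -0.02 (16, 0.177), MHC class II genes at -0.24 (8, 0.156), inflammatory genes at -0.24 (17, 0.642), RAS-MAPK output genes at 0.18 (20, 0.967) and YAP-TEAD targets at 0.10 (16, 0.888). TGF-beta and BMP targets were at -0.03 (17 members, adjusted p = 0.748), hypoxia genes at 0.03 (21, 0.967), p53 and senescence genes at 0.14 (17, 0.710), unfolded protein response genes at -0.06 (17, 0.710), cholesterol synthesis genes at 0.19 (18, 0.967) and immediate early genes at -0.09 (20, 0.710). The Wnt list passed as lower without Arid1a-deficient replicate 2 (median -0.93, adjusted p = 0.0437), and its median was -0.38 with normexp, -0.26 with every probe on its own and -0.47 with the mean over probes. The YAP-TEAD median lay between 0.0076 without Arid1a-deficient replicate 1 and 0.21 without Brg1-deficient replicate 1. The MHC class II median was -0.13 without Arid1a-deficient replicate 2, -0.42 without Brg1-deficient replicate 2 and -0.09 without Brg1-deficient replicate 3. The fry test for changes in either direction passed for the inflammatory (adjusted p = 0.000233), PI3K and mTOR (0.000280), interferon (0.00709), SWI/SNF subunit (0.0107), MHC class II (0.0147), TGF-beta (0.0168), cell cycle (0.0177) and Wnt lists (0.0467). It does not ask whether a list changes more than other genes, and 4815 of all 27500 tested genes had an unadjusted limma p under 0.05. These passes therefore single out no program. The SWI/SNF list also holds both targeted genes. Of the 31 lists that did not pass camera, the medians of 21 changed sign when 1 array was left out. The TGF-beta and unfolded protein response medians turned above 0 with normexp (0.04 and 0.08). With genes near background at their bound, the Wnt median was -0.63, the squamous 0.39, the intestinal 0.21 and the hepatocyte 0.56. The mean of the p53 and senescence, RAS-MAPK, duct, smooth muscle and ribosomal lists was above 0 while camera, which compares a list with all other genes, put them lower.

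Of the cell type markers that did not pass, hepatocyte genes had a median of 0.89 over 13 members (camera adjusted p = 0.0786), 11 of them higher and 2 lower. Alb, serum albumin, was at -0.48 against -4.52 (well above background in 1 of the 3 Brg1-deficient samples). Trf, transferrin, went the other way, with a log2 difference between -2.39 and -1.74 when 1 array was left out. The list passed as higher with median scaling (adjusted p = 0.0479), with the mean over probes (0.0409), without Arid1a-deficient replicate 1 (0.0432) and without Brg1-deficient replicate 1 (0.0324) or 2, and its median was 0.39 without Brg1-deficient replicate 3, 0.15 with normexp, 0.38 with no filter and 0.36 where a signal well above background was required on all arrays. Lymphocyte and plasma cell markers had a median of -0.05 over 19 members (adjusted p = 0.652), among which Jchain, the joining chain of secreted antibodies, was at 0.88 against 2.90. Smooth muscle and pericyte markers had a median of 0.10 over 11 members (adjusted p = 0.911), neutrophil markers one of -0.30 over 9 (0.642), tuft cell markers one of -0.29 over 15 (0.326) and islet markers one of -0.13 over 21 (0.911). The islet list passed as lower without Arid1a-deficient replicate 1 (median -0.97, adjusted p = 2.94e-06) and as higher without Arid1a-deficient replicate 2 (0.69, 0.000181). The tuft list passed as lower without Arid1a-deficient replicate 1 (-0.82, 0.0156) and had a median of 0.36 without Arid1a-deficient replicate 2. The technical lists, ribosomal proteins (0.09 over 45 members, 0.967) and sex-linked genes (-0.06 over 4, 0.913), did not pass either.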

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

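Of the tests in this part, those on the median difference of the control probes and on pairs of Brg1-deficient arrays were chosen only after the result was seen. Control probes with no mouse target, which no comparison uses, gave signal on these arrays. ERCC spots were well above background in 32.5% of cases on the Arid1a-deficient arrays and in 16.0% on the Brg1-deficient arrays (means over arrays), and E1A spots in 34.1% and 20.8%, while the spots of the negative control probe were well above background in 0% on every array.

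Dim genes read higher on the Arid1a-deficient arrays, with a shift of 0.35 in the dimmest 5500 tested genes. Brighter nonspecific signal on the slide of the Arid1a-deficient arrays may contribute, since the 106 ERCC and E1A probes had a median difference of 0.28 (interval 0.10 to 0.55) and their array medians did not overlap between slides. That interval includes both the shift of the dim genes and smaller values. The negative control probe was not brighter on that slide. Its median processed signal, unscaled, was 2.05 and 1.94 on the Arid1a-deficient arrays and 2.11, 2.22 and 2.16 on the Brg1-deficient arrays. The brighter signal was thus seen on the ERCC and E1A probes and not on every probe without a mouse target. A lower overall signal of the Brg1-deficient replicate 3 array may account for part, since without it the shift of the dimmest genes was 0.17 (interval 0.12 to 0.20). A greater readout of silent genes in the Arid1a-deficient epithelium stays open: genes of the brightness of the control probes shifted less than those probes (0.03 against 0.37, gap -0.32, bootstrap 95% interval -0.41 to -0.27), but they lacked the shift of the dim genes, so that the gap decides nothing, and slide and genotype cannot be told apart.

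Genes on in one genotype and near background in the other, meaning well above background on all arrays of one group and on none of the other, numbered 1074. Of these, 82.3% were on in the 2 Arid1a-deficient arrays and off in the 3 Brg1-deficient arrays. With as many arrays on both sides, against pairs of Brg1-deficient arrays the share was 68.8% (exact binomial 95% interval 66.4 to 71.2) without Brg1-deficient replicate 3, 85.4% without replicate 2 and 83.1% without replicate 1. Brighter nonspecific signal on the Arid1a-deficient slide, seen on the ERCC and E1A probes but not on the negative control probe, could give such an excess. It cannot be told apart from genotype. Of the 270 tested olfactory receptor genes, a family picked after its values were seen, 63 were on in the Arid1a-deficient arrays only and 3 in the Brg1-deficient arrays only. Over all 27500 tested genes these counts were 884 and 190. The receptor counts set 2 arrays against 3 and were not repeated with as many arrays on both sides. A chromosome segment of another strain around Ifi202b remained open: 3.55% of 197 neighbouring genes were of this kind, against 3.43% of the other named genes (one-sided Fisher's exact p = 0.518). That count left out Ifi202b itself and its neighbours Vangl2, Cd48 and Cadm3. Passenger segments of another strain around Arid1a and Smarca4 remained open as well, at 3% of 400 neighbours against 3.46% (one-sided Fisher's exact p = 0.729). A difference between the genotypes stays open and untested, above all for the 190 genes on in the Brg1-deficient arrays, among them most of the called genes.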

How the results depend on the processing

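Cyclic loess was the only alternative chosen after seeing the data. The median of the fibroblast list stayed below 0 under all alternatives and past the threshold under all except an estimated correlation (adjusted p = 0.599) and fry (adjusted p = 0.198), both at the same median of -1.38. The targeted probes kept their direction and called 0 probes throughout. The genes differing between the genotypes numbered 3 with normexp (1 higher, 2 lower), 2 with the series table (0 and 2), 0 with no filter (0 and 0, 5727 at an unadjusted p under 0.05), 3 with a signal well above background on all arrays (0 and 3), 27 with every probe on its own (5 and 22), 3 with an intensity trend and robust eBayes (0 and 3), 462 with array weights (161 and 301, from weights that did not converge), 3 with a floor (0 and 3) and 34 with cyclic loess (4 and 30), and quantile normalization called 5 higher. The share called higher was 20% in the main setting, 33.3% with normexp, 34.9% with array weights and 0% with the series table, and at an unadjusted p under 0.05 it was 60.8%, against 48.3% with normexp, which moved the median of all genes by -0.11, and 50.3% with cyclic loess. With the replicate block 0 genes passed (0 higher, 0 lower, 0 members of lists, 4051 genes at an unadjusted p under 0.05, 47.5% of them higher), cell cycle genes passed as higher, and the EMT, adipocyte and endothelial calls were lost (medians -0.29, -0.98 and -0.49), where 1 residual degree of freedom was left. Since 1 genotype alone has a replicate 3, the block fits that array exactly. Its differences therefore equal those without Brg1-deficient replicate 3 and are no separate result. Only 2 numbers were shared, and same-numbered arrays deviated with correlations of 0.12 and -0.15. The deviations of the 2 Arid1a-deficient arrays mirror each other by construction, so these correlations can show little about pairing. The arrays were not treated as paired. Leaving out single arrays gave 0 to 0 genes in total, higher and lower alike, 0 to 0 list members and 5 to 11 lists, the lone remaining Arid1a-deficient array being assumed to vary like the others. The 8 list shifts became 4 with normexp, quantile normalization, no filter and cyclic loess, 3 with all arrays well above background, 5 with every probe on its own and on ranks, and 0 with an estimated correlation and fry. Called list members numbered 1 in the main setting, 16 with array weights, 2 with cyclic loess and 0 with normexp, median scaling, the series table, no filter and the mean over probes. The cause of these changes was not tested. A slide block was not run, since each genotype had a slide of its own, and near background the signals bound differences without measuring them.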

Other observations

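Of the tests in this part, those on markers of other cell types and with cyclic loess were chosen only after the result was seen. In several cell type lists single samples stood apart, and whether a list followed a sample or the genotype was not tested. Several islet hormone genes were lower in Arid1a-deficient replicate 2 than in the other samples. Gcg, glucagon, was at 4.81 and -2.71 in the Arid1a-deficient samples and at 4.42, 4.38 and 5.0 in the Brg1-deficient samples, and Ins2, insulin, at 8.89 and 2.49 against 7.57, 6.71 and 7.55, whereas Sst, somatostatin, was at 5.84 and 5.47 against 5.21, 5.37 and 5.36. The median deviation of the islet list from the mean over arrays was 1.11 in Arid1a-deficient replicate 1 and -1.08 in Arid1a-deficient replicate 2. Erythroid genes deviated by 2.39 in Brg1-deficient replicate 2 and by -2.39 in Arid1a-deficient replicate 1. The stomach-type genes Pgc and Psca differed between the Arid1a-deficient samples, Pgc being at -0.92 and 3.83 and Psca at 2.39 and 8.77, while the Brg1-deficient samples lay between 3.77 and 4.76 and between 5.04 and 6.31.

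In a principal component analysis of the tested genes, the first component (41.4% of variance) separated the genotypes. The second (30.1%) set Arid1a-deficient replicate 2 and Brg1-deficient replicate 3 (-71.2 and -71.3) against the others (73.0, 27.9 and 41.7). The Arid1a-deficient arrays correlated with each other at 0.932 over genes, and the closest pair between genotypes at 0.930.

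The lower fibroblast and stellate cell markers in Arid1a-deficient IPMN were weighed against technical explanations. Fewer non-epithelial cells of every kind might move their markers alike, though markers of different cells need not move equally. The fibroblast median lay below that of 89 markers of other non-epithelial cells (-0.57) by a gap of -0.81 (bootstrap 95% interval over genes -1.30 to -0.38). Among markers well above background on all arrays the gap was -0.86 (-1.34 to -0.45). These intervals treat genes as independent and do not measure the spread between animals. The macrophage, endothelial, adipocyte and erythroid lists also passed as lower with the preset correlation, and the neutrophil, lymphocyte and smooth muscle lists did not. Under all alternatives the macrophage median stayed between -0.77 and -0.49. The gap therefore leaves a general but unequal loss open. Against single lists, the interval of the gap lay below 0 for the endothelial, macrophage, neutrophil, lymphocyte and smooth muscle lists. It included 0 for the adipocyte (-1.07) and erythroid lists (-1.67), so that a fall of equal size in these 2 lists stays open. The brightness-dependent difference ran upward, from a median of 0.40 in the dimmest of 10 groups of genes to 0.04 in the brightest. That is against the direction of the fibroblast markers, which argues against it as their cause. Cyclic loess, which removes such a trend, could therefore hardly change their median, which was -1.40 after it (interval -1.76 to -1.04). It does not bear on other differences between the slides. The slide and scan batch cannot be told apart from genotype, since 0 slides held both groups. A hypothesis that stays open and untested is that the samples held fewer fibroblasts, or fibroblasts with less matrix expression, in Arid1a-deficient lesions. Fibroblast counts in lesions of both genotypes, or arrays of both genotypes on the same slide, would be needed to test it, and the dissection of each epithelium could give the same pattern. The abundant collagen gene Col1a2, a member of the list, was at 2.99 against 4.76.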
